A study of Drosophila melanogaster with 4 samples.

How the data were processed

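Chromatin from whole 5-day-old flies was immunoprecipitated with an antibody against H3K27me3 and sequenced together with input chromatin, per the labels. The 4 libraries were grouped by diet (glucose or galactose) and by kind (IP or input), with 1 library per group. The series design text mentions a pair of replicates per condition, but the labels analysed here give 1 library for each group, so no test across replicates was made.

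All values came from 1 deposited table with 8159 rows, in which 644 rows repeated a region that overlapped more than 1 gene, leaving 7515 distinct regions. Per the file headers, the authors deposited the read count of each region in each library, RPM (reads scaled to library depth), the fold enrichment of IP over input for each diet, a log2 fold change, and whether a region was called from the glucose or the galactose IP. The deposited RPM equalled the count plus 1 read divided by a constant per library, and that constant was taken as the depth. The deposited fold enrichment equalled the ratio of IP to input RPM, with a largest gap of 5.11e-15. The authors' deposited log2 fold change was that of glucose over galactose, and its sign was turned here so that positive values mean more in galactose. No fold enrichment in either diet was under 1. Whether regions were filtered on this is not stated, and such a filter would limit the ratios and the counts of regions called from 1 diet. MACS2 and FastQC are named in the submitters' processing notes, without a version. The aligner, the genome build, and the calling thresholds are not given in the sources used here. Coordinates are printed as the table gives them, and whether the starts count from 0 or from 1 is not stated, so widths are end minus start. Of 1823 named genes, 98.6% had the same start or end as in RefSeq's Release 6 plus ISO1 MT assembly. Columns of values that belong to no sample numbered 0.

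The main measure, a log2 ratio of galactose over glucose fold enrichment per region, was the ratio in the table's own scaling. Its distribution and the number of regions at least 2-fold apart were described without p-values, since regions are not replicates. Exact conditional intervals (95%) were computed for single regions and approximate ones for the mean over a gene's regions, from the counts. They cover counting error only, and PCR copies are not removed from them. The median counting standard error of a region's log2 ratio was 0.30, and the SD over regions was 0.56. Each region was placed by the annotation the table gives: exon, UTR, intron or outside genes. A region with several annotations took the first that applied, in the order 5' UTR, 3' UTR, exon, intron, outside genes. This favours UTRs and exons where a region overlapped more than 1 gene.

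A gene took the mean over the regions that overlapped it or had its start site as the closest one. Of 6101 gene identifiers 2925 had a symbol in the table and 33 more were named through identifiers listed as synonyms in RefSeq's table, so the background was 2958 genes, and 3143 identifiers without a symbol stayed out of the lists. The 18 gene lists covered Hox genes, other Polycomb targets, Polycomb and Trithorax group genes, metabolic and stress pathways, housekeeping controls and tissue markers, and were fixed before the data were examined, as were the design, the named-gene rule and most of the alternatives. A list's median was given as a percentile among 10000 random lists of the same size, matched on mean level in 10 bins for the log2 ratio and unmatched for the fold enrichments, for lists with at least 3 genes. Gene Ontology terms from the table with 20 to 200 genes were compared with 2000 random lists, a step added after the data were seen.

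The named genes were, for each direction, the 10 genes with the largest log2 ratio among regions with a mean level at or above the median, 1 region per gene, the 5 genes with the highest mean level, every Hox and Leloir gene, and the highest and lowest member of each other list. Genes without a symbol were counted but not named. A gene named outside this rule is marked as such in the text.

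The calculations were tested on simulated counts for the 7515 regions at the real depths, with 200 regions changed 2-fold. All of them (100%) came out with the right sign and 50.5% at least 2-fold apart, approximate intervals held the true ratio in 95.2% of regions, and exact intervals in 98% of 200 trials. Of 200 simulated lists of 15 genes without a shift, 3% fell outside the central 95%, and 99.5% of lists shifted by 0.5 on the log2 scale fell above it. The simulated counts held counting error alone and no calling of regions. In the real libraries the input log2 ratio had a variance of 0.101, against 0.064 from counting error. The simulated lists held independent values, and most of the lists tested were shorter, so these rates need not hold for the real data.

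The alternatives were median-centring, scaling to the same total, a pseudocount of 1 RPM, IP reads alone, limits of 1.5-fold and 3-fold, regions of at least 500 bp, the stronger part of the regions, a higher level, other ways of assigning or matching genes, no X-linked genes, regions called from both diets, names added by gene coordinates, and genes with the same regions counted once. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.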

Results

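H3K27me3, the histone mark set by the Polycomb repressive complex, was profiled by chromatin immunoprecipitation and sequencing in whole 5-day-old Drosophila melanogaster that had been fed glucose or galactose. The series title places the work in a study of hormesis across generations and inherited resistance to aging, and the comparison asks where the mark differs between the sugars. Each diet had 1 immunoprecipitated (IP) library and 1 input library, 4 libraries in all, so no difference between the diets below has a replicate check. The depths were 26.4 M reads for the glucose IP, 18.0 M for its input, 13.2 M for the galactose IP and 10.8 M for its input. The glucose IP was 1.99 times as deep as the galactose IP. A region held a median of 183 reads in the glucose IP and 100 in the galactose IP, and 94 and 55 in the inputs. Counting intervals below are 95% intervals that cover counting error only and compare these libraries, not the diets.

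More regions were called from the galactose library than from the glucose library. The authors' table held 7515 distinct regions, of which 4591 were called from galactose (median width 325 bp, 1854 kb covered) and 4148 from glucose (228 bp, 1175 kb). A total of 1224 regions were called from both diets, 3367 from galactose alone and 2924 from glucose alone. Shared regions made up 16.3% of all regions, 29.5% of the glucose calls and 26.7% of the galactose calls. Shared regions had a median width of 379 bp. The table gives merged regions and not each diet's own peaks, so merging alone widens shared regions, and the widths and kb per diet include it. The median fold enrichment of IP over input was 1.31 in glucose and 1.55 in galactose. In all, 96 regions reached 2-fold in glucose and 1479 did in galactose, and the maxima were 3.40 and 4.22. Regions held 6.82% of the glucose IP reads (Wilson interval 6.81 to 6.83) against 5.40% of its input reads (5.39 to 5.41). They held 9.05% of the galactose IP reads (9.03 to 9.06) against 5.10% of its input reads (5.09 to 5.11).

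The highest mean level over both diets was found beside CG6481 (X, 18520689 to 18521071, outside genes), with a fold enrichment of 1.98 in glucose and 3.77 in galactose. The next region belonged to a gene with no symbol in the table and had 1.42 and 4.22. CG32486 (3L, 3070125 to 3070533, exon) ranked behind it with 1.80 and 3.58. Pde1c, a cyclic nucleotide phosphodiesterase gene (2L, 11818555 to 11818914, exon), had 1.42 and 3.71. The adenylyl cyclase gene rut had a region at its 5' UTR (X, 14825934 to 14826137) with 2.24 and 2.70. Its counting interval of the log2 ratio, −0.93 to 1.74, gave no direction.

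**Figure D1:**
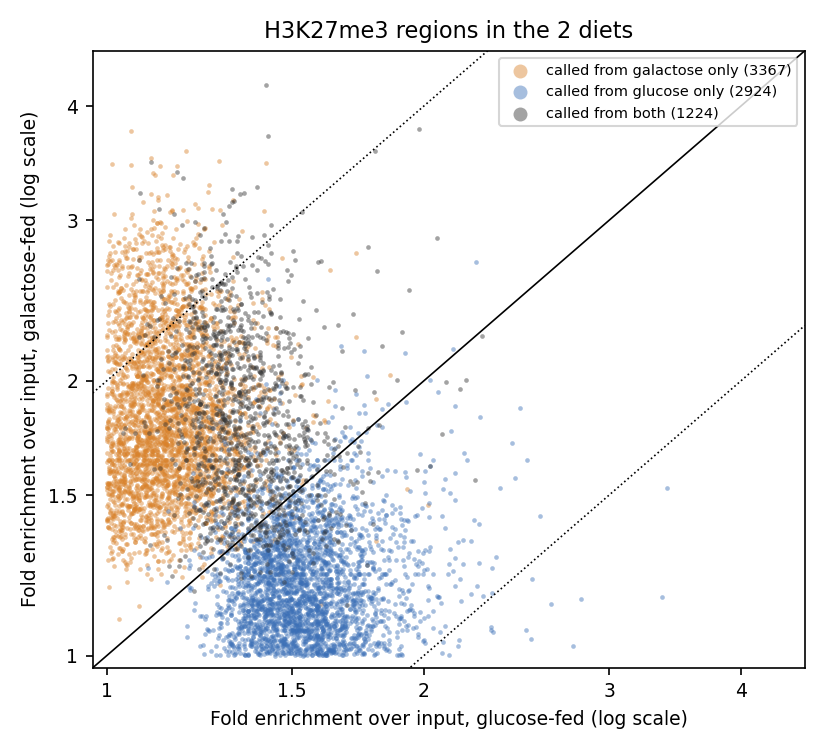
Fold enrichment of IP over input in glucose-fed flies (x axis, log scale) against galactose-fed flies (y axis, log scale) for the 7515 regions, coloured by the library they were called from; the solid line marks equal values and the dotted lines a 2-fold difference. Regions called from galactose alone had a median log2 ratio of 0.64, with 19 of 3367 below the line, and regions called from glucose alone −0.35, with 229 of 2924 above it; the excess above the upper dotted line, 643 regions against 16 below the lower one, turns to 27 against 718 when the libraries are scaled to the same total.

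Galactose fold enrichments were at least 2-fold above those of glucose in 643 regions, and glucose was at least 2-fold higher in 16, a balance that turned to 27 against 718 when scaled to the same total. The largest ratio was that of Syn, which encodes the synaptic vesicle protein synapsin and had a fold enrichment of 1.06 in glucose and 3.75 in galactose at its 5' UTR (3R, 10195589 to 10196153), a log2 ratio of 1.83 (counting interval 1.38 to 2.31). A region beside a gene with no symbol came next with 1.77. rg, which encodes a protein kinase A anchor protein, had 1.71 (1.17 to 2.29) at its 5' UTR (X, 5187061 to 5187446). The gene sif, a guanine nucleotide exchange factor active at synapses, had 1.61 (0.99 to 2.29) in an exon (3L, 5731423 to 5731758). Exons of the histone gene repressor Hers (1.65), the Pax-family regulator toe (1.61), the Wnt ligand gene Wnt2 (1.59), CG4341 (1.60) and CG3731, which encodes a core subunit of respiratory complex III (1.63), made up the rest of the named genes in this direction. The other 2 of the 10 genes had no symbol. By IP reads alone the named genes lay between 0.94 (CG3731) and 1.14 (CG4341). The mean over all regions of a gene was lower for those with several, down to 0.43 over 8 regions for toe, which is below 0 scaled to the same total.

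In the other direction the largest log2 ratio at a named gene was −1.44 (−2.47 to −0.45) at Trf2, a TBP-related general transcription factor gene, in an exon (X, 8409932 to 8410182), where fold enrichment was 2.77 in glucose and 1.02 in galactose. CG11825 had −1.29 outside genes, 114 bp from its start site. Sesn, which encodes the TOR inhibitor sestrin, had −1.23 (−2.31 to −0.17) at 39 bp from its start site (2R, 23713745 to 23713977). The mitotic kinesin gene cmet had −1.13 (−1.69 to −0.59) in an intron (2L, 11268479 to 11268875). A region closest to the ecdysone-induced regulator Eip74EF (3L, 17590878 to 17591105) had −1.21 (−2.05 to −0.43), although its IP reads alone gave 0.10. IP reads alone gave −0.81 for Trf2, −0.49 for CG11825, −0.93 for Sesn and −0.62 for cmet. Other regions of 3 of these genes went the other way as deposited: the mean was −0.055 over 2 regions for Sesn, 0.15 over 3 for cmet and 0.30 over 6 for Eip74EF, all below 0 scaled to the same total. The other 5 of the 10 genes had no symbol. In both directions the genes were picked for their extreme ratios among many regions, which the counting intervals do not allow for.

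Over all regions the median log2 ratio of galactose over glucose fold enrichment was 0.31 (quartiles −0.26 and 0.68), and 4662 regions (62.0%) were higher in galactose. The direction followed the library a region was called from. The median was −0.22 over regions called from glucose, 0.60 over those called from galactose and 0.42 over those called from both. All 643 regions at least 2-fold higher in galactose had been called from galactose and all 16 in the other direction from glucose alone. No region in the table had a fold enrichment under 1 in either diet, and a filter on this, which is not stated, would limit the ratios and these counts. Scaling the libraries to the same total over the regions subtracted 0.48 from every log2 ratio and turned the balance. It left 39.0% of regions higher in galactose and 27 regions at least 2-fold higher against 718 lower. Centring on the median gave 125 against 234. The ratio of IP reads alone had a median of 0.22 and gave 314 against 22. The counting interval lay above 0 for 2569 regions and below 0 for 188. Counting error alone produced 18 regions at least 2-fold apart in each direction in simulated unchanged data. That simulation was centred on a log2 ratio of 0 and the real ratios on 0.31. The 16 regions higher in glucose therefore cannot be set against it. After median-centring, the 125 regions higher in galactose and the 234 higher in glucose both exceeded 18. In the same simulation 4.76% of unchanged regions had an interval that excluded 0.

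Coding and untranslated sequence carried most of the regions and most of the galactose excess. Exons held 4646 regions (61.8%), 5' UTRs 446, 3' UTRs 407 and introns 899, while 1117 lay outside genes. The median log2 ratio was 0.60 in 3' UTRs, 0.44 in 5' UTRs, 0.35 in exons, 0.13 in introns and −0.0021 outside genes. Over exon and UTR regions it was 0.38, against 0.05 for the other regions. Scaled to the same total, the medians were −0.10 and −0.44, in the same order. Among regions called from both diets they were 0.46 and 0.24. Part of the gap lay in the inputs, whose median log2 ratio of galactose over glucose was −0.10 in exon and UTR regions and 0.08 in the others. The IP libraries alone gave 0.24 and 0.15. In glucose the exon and UTR regions had the lower median fold enrichment (1.29 against 1.39), and in galactose the higher one (1.60 against 1.44).

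The X chromosome held 1857 regions, 24.7% of all, against 15.8% of the protein-coding genes. It had the highest median log2 ratio of the arms, 0.42, compared with 0.28 over the autosomal arms of chromosomes 2 and 3. Its IP reads alone gave 0.24 against 0.21 on those arms, and its input reads −0.16 against −0.03. The X had 20.5 input RPM per kb in glucose and 17.7 in galactose. Arms 2L, 2R, 3L and 3R had 20.4 to 21.1 in glucose and 19.8 to 20.4 in galactose. Whether the sex makeup of the flies differed between the diets was not tested, and these values alone cannot decide it. The fourth chromosome, a small and largely heterochromatic chromosome, went the other way in its log2 ratio. Its 49 regions had a median of −0.30 and fold enrichments of 1.58 in glucose and 1.22 in galactose. Of these regions 39 were called from glucose alone. The eye regulators ey and toy on this chromosome had −0.31 (−0.58 to −0.04) over 6 regions and −0.68 (−0.91 to −0.45) over 1 region. By IP reads alone ey had −0.087, and toy had 0.54, the opposite direction, with an input log2 ratio of 1.22. Both were named after the pattern of the chromosome was seen. Scaled to the same total, the medians of all 6 arms were below 0, from −0.06 on the X to −0.78 on the fourth chromosome.

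**Figure D2:**
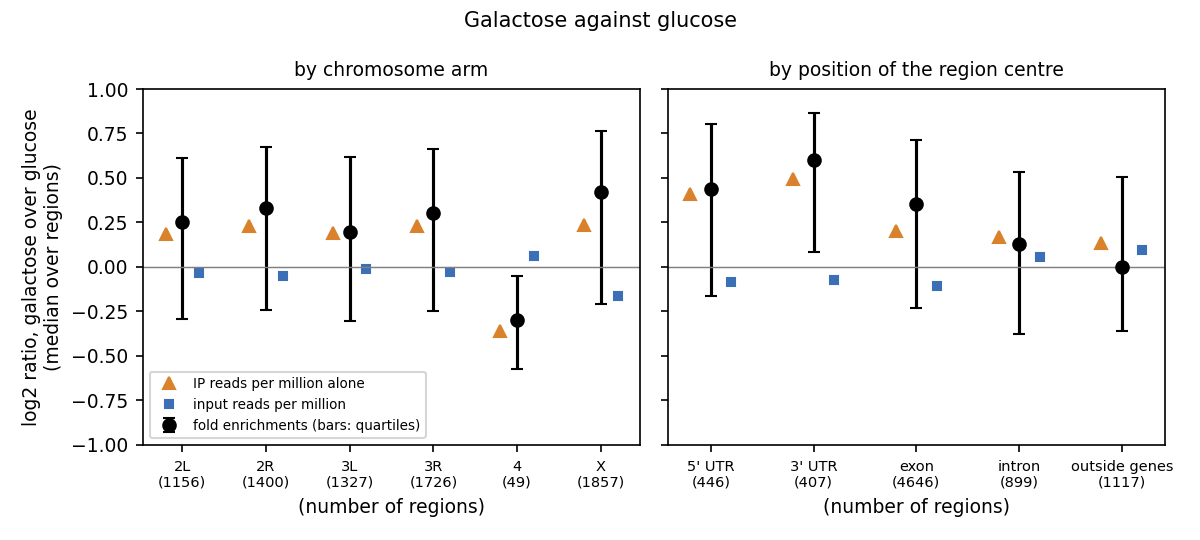
Median log2 ratio of galactose over glucose by chromosome arm (left) and by the annotation at the region centre (right), with the number of regions in parentheses; circles show fold enrichments with bars for the quartiles, triangles the IP RPM alone and squares the input RPM. The fourth chromosome lies at −0.30 and the X at 0.42, and 3' UTRs at 0.60 and regions outside genes at −0.0021; scaled to the same total, every circle moves down by 0.48, which puts all arm medians below 0.

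Hox genes, the homeotic selector genes that are textbook Polycomb targets, lay inside the central 95% of random lists by their log2 ratio. Of the 8 Hox genes, 6 had a region and a symbol in the table, and 5 of them (Antp, lab, Abd-B, Ubx and abd-A) were higher in galactose with counting intervals above 0. The 21 regions of the 6 genes included 18 called from galactose alone, 2 from glucose alone and 1 from both. The mean log2 ratio over a gene's regions was 0.89 (0.48 to 1.31) for abd-A, 0.88 (0.60 to 1.16) for Ubx, 0.64 (0.37 to 0.92) for Abd-B, 0.59 (0.35 to 0.83) for Antp and 0.59 (0.35 to 0.83) for lab. Each stayed above 0 when 0.48 was subtracted, though only for Ubx did the interval then stay above 0, and that of Dfd lay below it. Dfd had −0.026 (−0.34 to 0.28), and 0.17 by IP reads alone. The strongest single region was an exon of Ubx (3R, 16732647 to 16733309), with fold enrichments of 1.10 and 2.39 and a log2 ratio of 1.11 (0.80 to 1.43). The next were an exon of Abd-B (3R, 16931060 to 16931557), with 1.25 and 2.66, and an intron of abd-A (3R, 16826031 to 16826732), with 1.17 and 2.32. The list median of 0.62 lay at percentile 94.5 of random lists matched on level, and at 99.8 for IP reads alone. The median fold enrichment of the Hox genes was 1.82 in galactose, at percentile 88.6 of unmatched random lists. In glucose it was 1.17, at percentile 4.07, below the ribosomal protein genes (1.30, percentile 36.5). These percentiles mix the call classes, since 18 of the 21 regions were called from galactose alone.

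**Figure D3:**
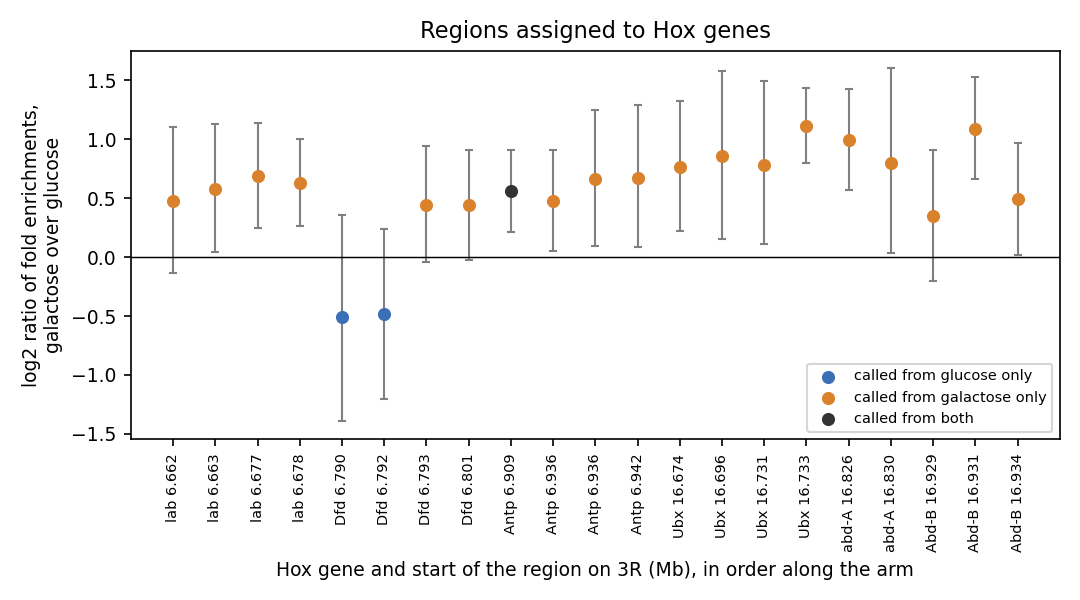
Log2 ratio of fold enrichment in galactose over glucose (y axis) for the 21 regions assigned to Hox genes, in order along arm 3R (x axis, start of the region in Mb); points are coloured by the library the region was called from and bars are exact 95% intervals for counting error. The exon of Ubx lies at 1.11 and the pair of Dfd regions called from glucose alone at −0.51 and −0.48; scaling to the same total would lower each point by 0.48.

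The other Polycomb target regulators, developmental transcription factor and signalling genes, differed in rank between the diets. Of the 115 such genes, 77 had a region under a symbol, and 101 did with names added by gene coordinates. Of the 77, 62 were higher in galactose. The counting interval lay above 0 for 47 and below it for 2. Scaled to the same total, 37 were higher in galactose and 40 in glucose, with 16 and 18 intervals clear of 0. Their median fold enrichment was 1.76 in galactose, at percentile 99.8 of random lists, and 1.28 in glucose, at percentile 7.67. The pair-rule gene eve had the highest log2 ratio, 1.30 (counting interval from 1.09), and the neural regulator ind the lowest, −0.73 (−1.48 to 0.01; −0.37 by IP reads alone). The eye gene eya had 1.06 (0.87 to 1.26) and the limb gene Dll 0.95 (0.69 to 1.21); both were picked from the list after their values were seen. Against random lists matched on mean level, the median log2 ratio of 0.47 (−0.020 scaled to the same total) stood at percentile 70.0, and against unmatched lists at 99.0. Against lists matched on the number of regions it stood at 98.5. By IP reads alone the median was 0.41 (97.4). With the region of highest level per gene the list was at 27.5, and without X-chromosome genes at 55.2. Polycomb and Trithorax group genes, which include writers of the mark and antagonists of Polycomb repression, had a median of 0.60 over 11 genes (percentile 73.5). Their ends were brm at 1.13 (0.65 to 1.61) and Set1 at −0.43 (−0.89 to 0.04). By IP reads alone Set1 had 0.51, the opposite direction, with an input log2 ratio of 0.94. Of 34 ribosomal protein genes, included as active genes, 15 had a region under a symbol, and 15 with names added by gene coordinates. They had fold enrichments of 1.30 in glucose and 1.53 in galactose, at percentiles 36.5 and 35.1. Their median log2 ratio was 0.40 (percentile 63.6; −0.083 scaled to the same total), from RpL18 at 0.93 to RpL3 at −0.46. IP reads alone gave 0.14 (24.1), and regions within 1 kb of the gene 0.17 over 12 genes (11.6).

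Metabolic and stress genes lay within the central 95% of random lists by their log2 ratios as deposited. The medians of all 6 such lists below were under 0 when scaled to the same total. Some left the central 95% under other settings. Heat shock genes, with Hsp22 and Hsp67Bb counted once because they share 1 region, were at percentile 0.98 (median −0.45, 5 genes) with regions within 1 kb of the gene. By IP reads alone they were at 1.12 (−0.29). Among regions called from both diets 3 of them were at percentile 0.20. Sugar sensing genes were at 2.04 by IP reads alone, and mitochondrial genes at 98.7 (0.91) without X-chromosome genes. No gene of the Leloir pathway, which converts galactose to glucose phosphate, had a region under a symbol in the table. Glycolysis and pentose phosphate genes had a median log2 ratio of 0.43 over 12 genes (percentile 49.8), with the pentose phosphate genes Pgd at 0.997 (0.63 to 1.36) and Zw at −0.37 (−0.77 to 0.04) at its ends. IP reads alone gave that list a median of 0.015 (percentile 3.92). Insulin, TOR and AMPK genes had 0.26 over 12 genes (28.5), from AMPKalpha at 0.86 (0.54 to 1.18) to Thor at −0.61 (−1.24 to 0.01). Sugar sensing and lipogenesis genes had −0.063 over 9 genes (4.69), from the amylase gene Amy-p at 0.88 (0.27 to 1.49) to ACC at −0.39 (−1.06 to 0.29). Mitochondrial genes had 0.40 over 12 genes (42.1), from the complex III gene CG3731 at 1.63 to the complex I gene CG9172 at −0.50. Oxidative stress genes had 0.15 over 8 genes (10.8), from the peroxiredoxin gene Jafrac1 at 0.86 to Trxr-1 at −0.49. With names added by gene coordinates they had 0.45 over 9 genes (58.7). Heat shock genes had −0.028 over 7 genes (15.9; −0.014 and 8.36 with the shared region counted once), from DnaJ-1 at 0.19 to Hsp22 at −0.49. Oxidative stress genes had a mean level over both diets at percentile 99.6 of random lists. In each diet alone they were near the middle, with 1.33 in glucose (51.8) and 1.56 in galactose (44.1). Part of the high ends lay in the inputs: IP reads alone gave Pgd 0.33, AMPKalpha 0.29 and Amy-p 0.52.

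Neuron and glia markers lay just above the central 95% of random lists as deposited, and a pair of short lists lay below it. The 8 neuronal genes had a median log2 ratio of 0.73 (percentile 97.9). They were inside the central 95% with the region of highest level per gene (96.9), within 1 kb (96.9), by IP reads alone (92.9), without X-chromosome genes (92.2) and with names added by coordinates (93.9). They stayed outside it against lists matched on the number of regions (99.2) and unmatched lists (98.6). They included the active zone gene brp at 0.99 (0.83 to 1.16), the vesicular glutamate transporter gene VGlut, named after its value was seen, at 0.90 (0.40 to 1.40) and Syt1 at −0.43 (−1.26 to 0.41). Immune genes had −0.44 over 4 genes (percentile 1.58, and 3.76 by IP reads alone), where Dif at −0.64 (−1.31 to 0.03; −0.32 by IP reads alone) opposed PGRP-LB at 0.87 (0.54 to 1.20). None of the 3 members with a negative ratio had an interval clear of 0. Testis markers had −0.27 over 3 genes (1.52), from aly at −0.59 (−1.17 to −0.01) to Mst98Ca at 0.89 (0.57 to 1.22). IP reads alone gave them a median of 0.34 (percentile 39.1), and they lay at percentile 4.62 with the region of highest level per gene and 21.8 against lists matched on the number of regions. Ovary markers had −0.053 over 8 genes (2.75), from stau at 1.05 to otu at −0.50 (−0.89 by IP reads alone). By IP reads alone the list had −0.13 and left the central 95% (2.13). Without X-chromosome genes the 3 left had 0.999 (99.7). Muscle markers had 0.40 over 5 genes (65.3; −0.082 scaled to the same total), from Zasp52 at 0.61 to bt at −0.029, which had 0.33 by IP reads alone. Of the housekeeping controls no actin gene had a region under a symbol, and the tubulin and histone genes had −0.42 over 3 genes (18.2), from alphaTub84B at −0.26 to His3.3B at −0.43, with the mean level at percentile 0.09. IP reads alone gave this pair −0.61 and −0.90. They gave the list a median of −0.61, at percentile 2.39 in 1 draw of random lists and 2.735 in another. Of the fat body and gut markers 1 gene had a region under a symbol, Mtp, with 0.37 (−0.43 to 1.18), and 1.43 by IP reads alone. With names added by coordinates 5 had one, with a median of −0.0061 (18.3). Of 16 lists with enough genes, 3 lay outside the central 95% of random lists where chance gives 0.8. None of the 3 did with gene names added by coordinates. Scaled to the same total, 3 of the 16 medians stayed above 0, those of the Hox genes (0.13), the Polycomb and Trithorax group genes (0.11) and the neuronal genes (0.25).

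**Figure D4:**
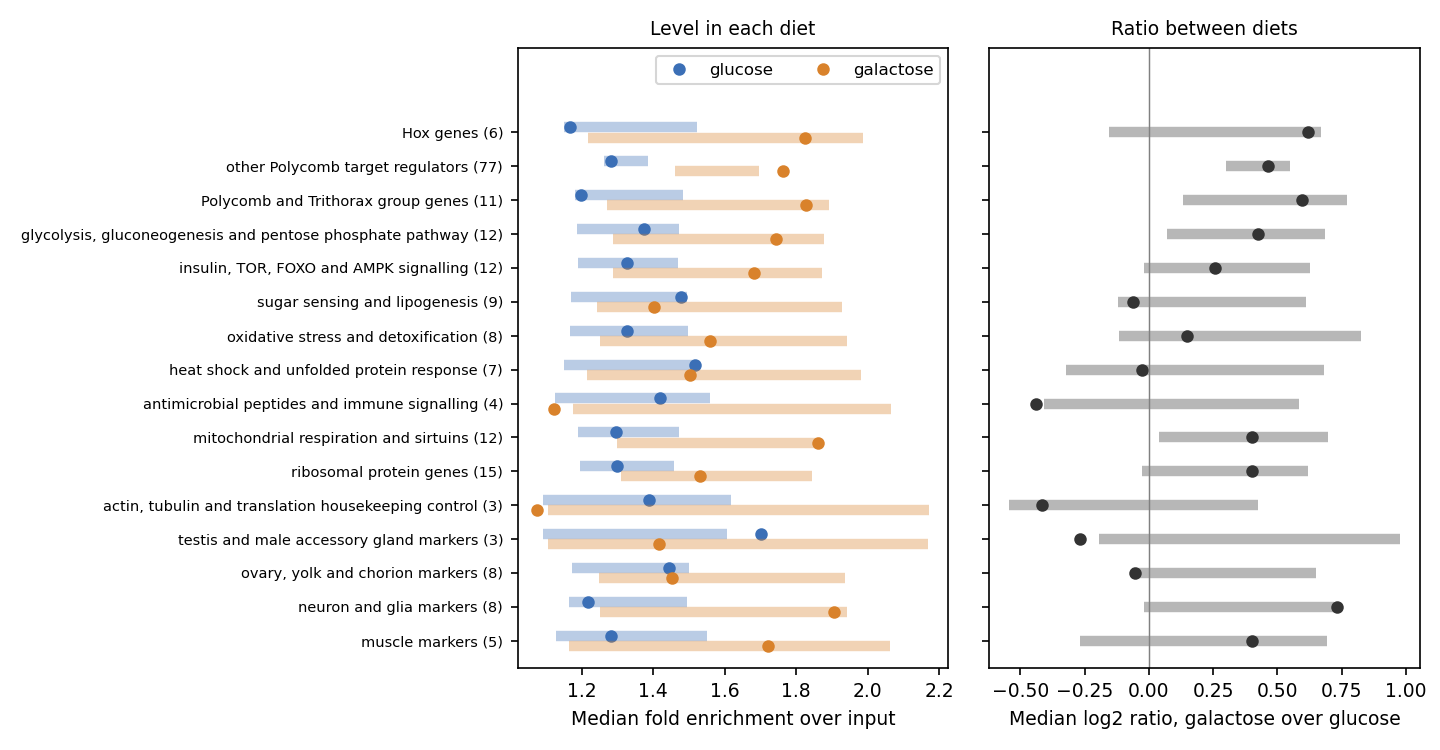
Median fold enrichment over input in glucose and galactose (left) and median log2 ratio of galactose over glucose (right) for the 16 gene lists with at least 3 genes, with the number of genes in parentheses; thick bars span the central 95% of random lists of the same size. Other Polycomb target regulators lie at 1.76 in galactose and 1.28 in glucose, and neuronal markers at a log2 ratio of 0.73; scaled to the same total, all medians on the right move down by 0.48 and 3 stay above 0.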

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

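Restricting the level to regions called from both diets, the lists by IP reads alone, unmatched random lists, names added by gene coordinates and genes with the same regions counted once were chosen after the data were seen. Regions at or above 1 cut, the median over all regions of the fold enrichment in the library a region was called from, held 1501 glucose and 3057 galactose calls with 21.3% shared, and regions of at least 500 bp held 358 and 1097. Regions at least 2-fold higher in galactose and in glucose numbered 125 and 234 after median-centring, 27 and 718 scaled to the same total, 2363 and 477 at 1.5-fold, 10 and 0 at 3-fold, 79 and 0 among regions called from both, 314 and 22 for IP reads alone and 475 and 2 with a pseudocount. The share higher in galactose was 39.0% scaled to the same total, 63.2% for IP reads alone, 79.2% at a higher level and 88.6% among regions called from both. Centring and scaling to the same total each subtract 1 number from every ratio, which by construction moves these counts. The 1.5-fold and 3-fold limits move them by construction as well. For the rest the cause was not tested. Centred on the autosomal arms, 2L (−0.021), 3L (−0.078) and introns (−0.15) reversed. Lists outside the central 95% numbered 1 with the region of highest level per gene, 5 by IP reads alone, 0 with names added by coordinates and 1 among regions called from both; by level, 1 in glucose alone. The testis median reversed by IP reads alone (0.34) and with added names (0.11), as did Eip74EF by IP reads alone (0.10). Matching random lists on the number of regions, or not matching them, leaves a list's own median unchanged. These settings therefore gave 16 unmoved medians each by construction. Counting shared regions once changed only the heat shock list, so the medians of the other lists were fixed there too. Of the other list medians 115, these included, stayed within the compared spread and 17 moved. Among them 4 changed sign: the ovary median with the region of highest level (0.13), without X-chromosome genes (0.999) and among regions called from both (0.62), and sugar sensing among regions called from both (0.19). Scaling was not among these settings: of the 16 list medians, 7 above 0 as deposited were below 0 scaled to the same total and 2 after median-centring. Of the other values of named genes 59 stayed and 8 moved; 3 changed sign, all for the rut region, which had −0.045 after median-centring, −0.22 scaled to the same total and −0.77 by IP reads alone. A reciprocal overlap was not run, since the table gives merged regions and not each diet's own. No paired analysis was possible because each group has 1 library. With 55 input reads in the median galactose region, single ratios carry a counting error that limits them.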

Other observations

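Outside the fixed lists, genes were grouped by the Gene Ontology terms in the table, a step chosen after the data were seen. Against level-matched random lists, the terms at the high end were mostly of RNA processing, and those at the low end mostly metabolic. Other terms of both kinds, such as RNA binding and mitochondrion, lay between the ends. RNA-processing and metabolic genes were not compared directly. Of 186 terms, 5 had a median log2 ratio above percentile 99.5 of level-matched random lists and 4 below percentile 0.5, where chance gives 0.93 at each end if terms were independent, which overlapping terms are not. The high terms were regulation of alternative mRNA splicing (25 genes, 0.73), mRNA splicing via the spliceosome (69 genes, 0.56), mRNA binding (91 genes, 0.61), the precatalytic spliceosome (54 genes, 0.55) and axon (25 genes, 0.67). The low terms were lipid metabolic process (44 genes, −0.20), carbohydrate metabolic process (29 genes, −0.24), iron ion binding (24 genes, −0.14) and oxidation-reduction process (107 genes, −0.06). All 5 high medians stay above 0 when 0.48 is subtracted for scaling to the same total. The level used for matching includes the galactose fold enrichment. Against unmatched lists the 5 high terms stayed above percentile 99.5, and terms of gene regulation were above it too. Among these were sequence-specific DNA binding (100), negative regulation of gene expression (99.95) and chromatin binding (99.7). Of the low terms, iron ion binding was at percentile 1 of unmatched lists. By IP reads alone only mRNA binding (100) of the high terms stayed above percentile 99.5, and regulation of alternative splicing (99.1), mRNA splicing (99.0), the precatalytic spliceosome (96.5) and axon (92.6) fell below it. Several terms between the tails as deposited rose above it by IP reads alone. Among them were sequence-specific DNA binding (100, from 96.45), ventral cord development (100, from 95.7) and RNA polymerase II distal enhancer factors (100, from 97.6). Iron ion binding was then at 0.01 (4.35), and lipid, carbohydrate and oxidation-reduction terms were at −0.25 (percentile 0), −0.20 (1.60) and −0.09 (0).

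The levels restate these ratios. The carbohydrate term had a median fold enrichment of 1.45 in glucose, at percentile 99.3 of random lists, and 1.24 in galactose, at percentile 0.05. The fixed list of glycolysis and pentose phosphate genes did not share this, with 1.37 in glucose (73.4), 1.74 in galactose (85.7) and a log2 ratio at percentile 49.8. Genes of mRNA splicing via the spliceosome, which are broadly active genes, had 1.21 in glucose, below all 2000 random lists, and 1.73 in galactose, at percentile 98.3. Sequence-specific DNA-binding genes, 143 in number, had 1.27 in glucose (percentile 0.35) and 1.72 in galactose (100). This term was picked after its levels were seen. It was not among the terms in the tails against level-matched lists, with its log2 ratio at percentile 96.45.

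Of the tests below, the 3 on the 2-fold regions and the exon test on Polycomb targets were chosen only after the result was seen. The first pattern is the excess of regions at least 2-fold higher in galactose. Inputs as the whole cause of the excess as deposited are argued against, since IP reads alone gave 314 regions higher and 22 lower, 14.3 for each one lower (SD 3.15). A larger calling fold in the shallower galactose library stays open: regions at least 1.5-fold enriched at the lower end of their counting interval numbered 50 in glucose against 1632 in galactose as deposited, and against 251 scaled to the same total, 5.02 times as many (SD 0.78). A scale factor between the libraries stays open as well, since there were 0.53 regions higher for each one lower after median-centring (SD 0.06), an outcome that centring itself moves. A diet effect and a difference in IP efficiency were not tested, with 1 library per diet.

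The second pattern is the level at Polycomb target regulators. If the regions marked Polycomb targets in both diets, the list would stand high in each, and the lower of its percentiles was 7.67, in glucose (27.97 without X-chromosome genes). That percentile cannot decide the question, since the random lists held only genes with a called region. The median glucose fold enrichment was 1.52 in regions called from glucose alone and 1.13 in those called from galactose alone. Of the list's 246 regions, 67 were called from glucose alone and 118 from galactose alone, against 2924 and 3367 of all 7515. The list's mean level over both diets was at percentile 99.5, with galactose at 99.8. A preference for exons in both libraries stays open. Exon and UTR regions made up 71.2% of the glucose calls and 77.5% of the galactose calls. Their median fold enrichment differed from that of the other regions by −0.099 in glucose (resampling SD 0.011) and by 0.16 in galactose. These differences were taken within called regions and mix the call classes, so they cannot decide the question. Base composition was not tested, since no genome sequence was used here.

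The third pattern is the fourth chromosome, lower in galactose while other arms were higher as deposited. Inputs as the whole cause are argued against, since the median log2 ratio of IP reads there lay at −0.58 relative to the other arms (resampling SD 0.06). That value goes mostly with the call class: among regions called from glucose alone the IP difference was −0.13 (resampling SD 0.04). Whether the pattern comes from its regions being called mostly from glucose alone cannot be told apart from a difference of the chromosome: within that class its median differed from the other arms by −0.11 (resampling SD 0.07), and 39 of its 49 regions belong to the class. A diet difference was not tested, with 1 library per diet.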
